A study of Homo sapiens with 12 samples.

How the data were processed

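RNA was sequenced from 12 cultures of primary human airway epithelium grown at an air-liquid interface, a culture form in which the apical side of the cell layer faces air and the medium lies below. Per the labels' protocols, cultures of 6 donors with no known disease received either vehicle or recombinant human periostin, a secreted matricellular protein, on the basolateral side at 200 ng per mL for 72 hours. The labels give 6 control and 6 periostin libraries, and the libraries are named here by group and replicate number; libraries with the same number came from the same donor. Per the labels' protocols, libraries were made with a stranded mRNA preparation kit, and the series' design text names paired-end sequencing.

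Each deposited table lists 159998 RefSeq transcripts with a length, an effective length, an estimated count and a TPM value. Per the submitters' processing notes, kallisto 0.45.0 and the genome build GRCh38.p12 were used. The estimated counts deposited by the authors are kallisto's expected counts, which divide reads among transcripts that share sequence and need not be whole numbers. The TPM values deposited by the authors are these counts divided by effective length and scaled to the same total in each library. The lengths and effective lengths in the deposited tables are in bases, and the effective lengths were used only for the length-scaled alternative. The strand setting used for counting is not given in the sources used here. Reads from a gene and an overlapping or antisense neighbour, or from near-identical gene copies such as the KRT6, SPRR and AKR1C genes, are therefore uncertain in their assignment.

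Transcripts were joined to genes by RefSeq accession without its version, through a gene table of assembly GRCh38.p14, from which names and gene types but no coordinates were taken. Of the 159998 transcripts, 108640 matched a gene and 51358 did not. The matched transcripts held 90.78% of all estimated counts, between 90.22% and 91.26% per library, and 9.22% of counts were left out of the gene values. Nearly all counts on curated accessions matched (99.66% for NM and 99.05% for NR accessions). Predicted models matched less often, with 45.81% of the counts on XM and 18.39% of the counts on XR accessions. A gene's value therefore lacks the reads that kallisto placed on its unmatched predicted models. As a check, the unmatched transcripts were tested one by one in edgeR with the same design: of 12017 tested, 0 had an adjusted p under 0.05 and 245 had an unadjusted p under 0.05. Ribosomal RNA genes (37 genes, 1.52% to 6.7% of counts per library), XIST, TSIX and Y-linked genes were left out of every test and table. Mitochondrially encoded genes were not among the listed transcripts and were not analysed here.

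Total estimated counts ranged from 12.2 to 19.87 M (mega) per library, with a median of 18.12 M. The gene matrix held 34445 genes and 10.7 to 17.75 M counts per library. Estimated counts were summed per gene and rounded to whole numbers. Genes with low counts were removed with edgeR's filterByExpr on the 2 groups, which left 15219 genes, of which 13340 were protein-coding. Library sizes were normalised with TMM, and log2 CPM values (CPM, counts scaled to a common library size) used a prior count of 2.

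The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) of periostin against control with the donor as a block and a Benjamini-Hochberg adjusted p threshold of 0.05. The block follows from the labels, which state that cultures of the same donors received both treatments. The pairing also showed in the counts: deviations from the group means correlated between 0.33 and 0.45 for libraries with the same number and at most at 0.14 for libraries with different numbers, and 12 of the 12 libraries correlated best with their own number. No 2 libraries agreed within sampling noise, since chi-square per degree of freedom ranged from 5.23 to 71.93 over the 66 library pairs. Between-pair differences took 66.4% of the variance of log2 CPM, the groups took 5.3%, against 5.6% expected from the remaining spread alone, and 28.2% was left.

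Before the data were examined, 36 gene lists were fixed for airway cell types, other cell types a culture could hold, and pathways. The 31 lists with at least 5 tested members were tested with limma's camera (limma 3.58.1) at its preset correlation of 0.01, and with an estimated correlation and fry beside it. An exact two-sided sign-flip test of the 6 pair means, with 64 sign flips and a smallest possible p of 0.031, was added after the data were seen. The rule for named genes, also fixed before, took the 10 genes per direction with the smallest unadjusted p where fewer than 5 passed the threshold, up to 4 members of each list with the smallest unadjusted p, and POSTN, ITGAV, ITGB1, ITGB3 and ITGB5. Up to 4 members were taken for lists past camera and up to 2 for the others; the limit of 2 was set after the results were seen. The markers FOXJ1, KRT5, MUC5B, CFTR and BPIFA1 were chosen after their values were seen. Some list members that the rule takes are not reported here. POSTN had too few counts for the gene test and was compared with an exact paired sign-flip test of log2(TPM + 1).

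Alternatives were a fit with no replicate block, DESeq2 1.42.0, limma-voom, DESeq2's size factors, no filter on low counts, a filter of 10 counts in 6 libraries, length-scaled TPM counts, an adjusted p under 0.1, an absolute log2 fold change of at least 0.5, pseudocounts of 0.1 and 0.01 TPM for POSTN, each replicate pair left out in turn and, added after the data were seen, protein-coding genes only. The fits were tested on simulated data with the same library sizes and pairing, in which 50 genes were changed at each of 4 fold sizes among 14971 genes tested. For the periostin comparison, edgeR recovered 8 of 50 genes changed 1.25-fold, 20 of 50 changed 1.5-fold, 40 of 50 changed 2-fold and 46 of 50 changed 4-fold, with 13 false calls among the 14749 tested genes that were left unchanged. A further 26 genes of 1 list were shifted 1.25-fold in the same simulation, and 222 of the 226 changed or shifted genes passed the filter on low counts. Among simulated genes at 10 CPM or more, 18 of 26 changed 1.5-fold and 30 of 30 changed 2-fold were recovered. With this many changed genes, the adjusted p threshold is reached at a larger unadjusted p than where few genes change. These shares therefore overstate the chance of finding a few changed genes. Gene coordinates are from GENCODE release 29 on GRCh38, matched by symbol. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for joining and plotting.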

Results

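Gene expression was measured by RNA sequencing in primary human airway epithelial cultures exposed to basolateral periostin or to vehicle. There were 6 control and 6 periostin libraries, 1 of each from each of 6 donors. Total estimated counts were 17.2 ± 2.71 M in control (SD, n = 6) and 18.02 ± 1.03 M in periostin (SD, n = 6), with the lowest total, 12.2 M, in control replicate 4. Ribosomal RNA took 3.15 ± 1.84% of counts in control and 2.21 ± 0.39% in periostin (SD, n = 6 each). The single comparison in the design asks how the airway epithelial transcriptome differs after 72 hours with 200 ng per mL periostin.

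The transcriptomes of the periostin and control cultures were close, and no gene passed the threshold. The gene nearest to it was ATP2B1, which codes for a plasma membrane calcium pump, at 3.48 ± 2.94 CPM in control and 12.97 ± 8.20 CPM in periostin (SD, n = 6), higher in 6 of 6 pairs. In edgeR's quasi-likelihood test with donor as a block, 0 of 15219 genes had an adjusted p under 0.05, 0 higher and 0 lower, and 608 had an unadjusted p under 0.05, against 761 expected with no effect. The same count was 0 with limma-voom (606 genes at an unadjusted p under 0.05), 0 in edgeR with no replicate block (229 genes) and 2 with DESeq2 (400 genes). Of the 608 genes, 353 were higher and 255 lower with periostin. For the 9738 genes at 10 CPM or more, the 95% interval of the fold change lay within 2-fold either way for 99% and within 1.5-fold either way for 94.7%. In all 6 pairs 472 genes went one way, which is 3.1% of the genes tested, and chance gives 3.12%.

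**Figure D1:**
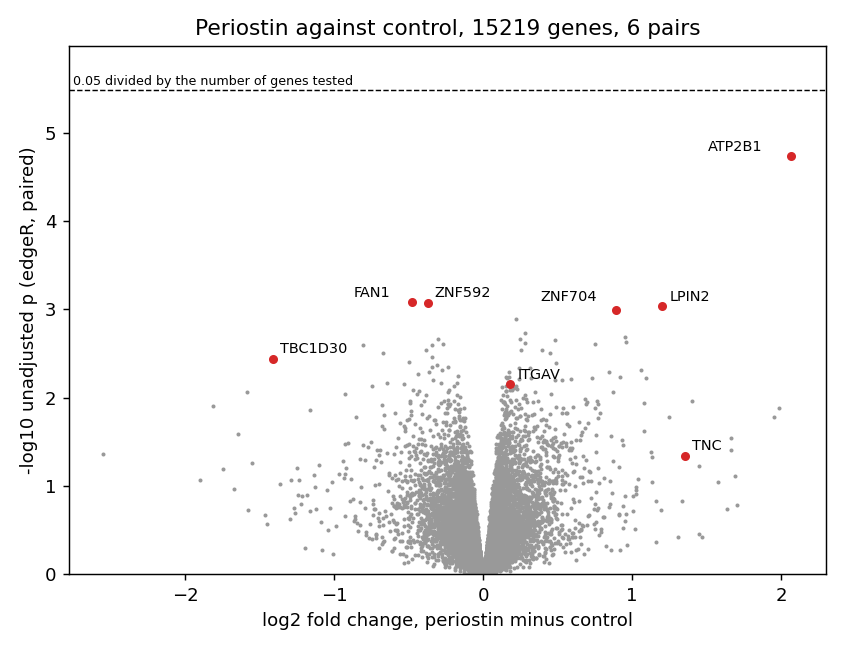
Log2 fold change of periostin against control (x axis) and the -log10 unadjusted p of edgeR's paired quasi-likelihood test (y axis) for 15219 genes, 1 point per gene, with 8 named genes in red. No point lies above the dashed line, which marks 0.05 divided by the number of genes tested; ATP2B1 lies nearest to it.

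The 10 genes with the smallest unadjusted p among those higher with periostin were ATP2B1, LPIN2, ZNF704, HSD17B11, ANGPT1, CRB1, PSPC1, ZNF692, SNHG21 and PAQR3. ATP2B1 (chromosome 12, 89588049 to 89709300, minus strand) had a log2 fold change of 2.07 ± 0.23 (SE) and an adjusted p of 0.28 in edgeR. DESeq2 gave ATP2B1 a log2 fold change of 2.11 and an adjusted p of 5.04e-09, and edgeR without a filter on low counts gave an adjusted p of 0.0239. Over all settings tried the adjusted p of ATP2B1 ranged up to 1, in the fit with no replicate block. Pair 4 held almost no counts on the 4 matched ATP2B1 models, with 0 CPM in control and 0.123 CPM in periostin. Any reads placed on unmatched predicted models are not part of these values. LPIN2, a phosphatidate phosphatase of lipid synthesis (chromosome 18, 2916994 to 3013315, minus strand), was at 7.55 ± 3.91 CPM in control and 16.4 ± 6.09 CPM in periostin (SD, n = 6), higher in 5 of 6 pairs, with an adjusted p of 0.952 in edgeR and 0.0175 in DESeq2. These LPIN2 counts lay largely on predicted models, since curated accessions held 30.8% of its matched counts in control and 5.1% in periostin, so the assignment between models is uncertain. ZNF704, a zinc finger gene, was at 4.75 ± 1.08 CPM in control and 8.90 ± 2.46 CPM in periostin. Angiopoietin 1 (ANGPT1) was at 14.7 ± 3.33 against 18.0 ± 4.50 CPM, and the steroid dehydrogenase HSD17B11 was at 41.8 ± 8.23 against 48.5 ± 9.19 CPM, both higher in 6 of 6 pairs. Log2 fold changes were 0.95 ± 0.21 for CRB1, 0.25 ± 0.06 for PSPC1, 0.48 ± 0.11 for ZNF692, 0.96 ± 0.22 for the noncoding SNHG21 and 0.28 ± 0.07 for PAQR3 (SE). CRB1 and SNHG21 lay near 1 CPM.

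Among genes lower with periostin the 10 smallest unadjusted p belonged to FAN1, ZNF592, SNORA57, ZNF335, SERTAD2-AS1, PTOV1, CHURC1, SNORA84, NDE1 and TBC1D30. FAN1, a nuclease of DNA crosslink repair (chromosome 15, 30903852 to 30943108, plus strand), was at 24.4 ± 4.89 CPM in control and 17.4 ± 2.44 CPM in periostin (SD, n = 6), lower in 6 of 6 pairs, with a log2 fold change of -0.48 ± 0.09 (SE) and an adjusted p of 0.952 in edgeR. Curated accessions held 78.5% of the 2211 FAN1 counts in control and 92.6% of the 1665 in periostin, so much of the difference lay on predicted models. The zinc finger gene ZNF592 was at 32.7 ± 5.23 and 25.4 ± 4.95 CPM, also lower in 6 of 6 pairs. TBC1D30 had the largest difference of the 10, a log2 fold change of -1.41 ± 0.33 (SE), from 2.32 ± 1.76 to 0.92 ± 0.79 CPM. Curated accessions held 22.6% of its matched counts in control and 89.3% in periostin, so its assignment between models is uncertain too. The small nucleolar RNA genes SNORA57 and SNORA84 had log2 fold changes of -0.30 ± 0.07 and -0.67 ± 0.16 (SE), and SERTAD2-AS1, an antisense transcript, had -0.81 ± 0.19. Reads of host or antisense transcripts were not told apart from these 3 genes here, so their values are uncertain. For ZNF335, PTOV1, CHURC1 and NDE1 the log2 fold change lay between -0.38 and -0.27.

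POSTN itself, the gene for the added protein (chromosome 13, 37562583 to 37598844, minus strand), was barely detected. Its TPM was 0.104 ± 0.083 in control and 0.044 ± 0.037 in periostin (SD, n = 6), and no library had more than 19 estimated counts. The exact two-sided sign-flip test of log2(TPM + 1) gave a mean difference of -0.077 ± 0.139 (SD of 6 pairs) and p = 0.219, with 4 of 6 pairs lower. Control replicate 1 held 19 of the 62 POSTN counts in all libraries, and without replicate 1 the mean difference was -0.024. Among the integrin subunits that bind periostin, ITGAV (chromosome 2, 186590065 to 186680901, plus strand) was at 232 ± 13.8 CPM in control and 263 ± 16.6 CPM in periostin (SD, n = 6), higher in 6 of 6 pairs, with an adjusted p of 0.952 in edgeR and an unadjusted p of 0.0071. ITGB1 was at 450 ± 48.6 and 473 ± 48.3 CPM and ITGB5 at 60.4 ± 7.13 and 59.3 ± 6.20 CPM. ITGB3 had 0 to 3 estimated counts per library and was not tested.

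The squamous and cornified envelope list, keratins and envelope proteins of stratified and wounded epithelium, was higher as a group with periostin: 15 of its 18 tested members were higher, with a median log2 fold change of 0.23 and an adjusted p of 8.65e-05 in limma's camera. The adjusted p was 0.875 with an estimated correlation. KRT6A (chromosome 12, 52487174 to 52493257, minus strand) was at 87.7 ± 82.2 CPM in control and 104 ± 62.1 CPM in periostin (SD, n = 6), with a log2 fold change within pairs of 0.45 ± 0.13 (SE). Log2 fold changes were 0.75 ± 0.24 for KRT13, 0.64 ± 0.22 for KRT16 and 0.54 ± 0.21 for SPRR1B (SE). Levels were low for KRT16, at 3.30 ± 3.56 and 4.22 ± 2.48 CPM, and SPRR1B, at 3.21 ± 3.80 and 4.07 ± 3.62 CPM. The most abundant member, SERPINB3, was at 2743 ± 736 CPM in control and 2750 ± 685 CPM in periostin, and KRT4 was at 174 ± 56.2 and 163 ± 44.9 CPM (SD, n = 6). No member passed adjusted over the list alone, where the smallest edgeR adjusted p was 0.113, and 6 members had an unadjusted p under 0.05. The mean of the list was higher in 5 of 6 pairs, by 0.24 to 0.60 on the log2 scale, and was -0.16 in pair 6, whose control had the highest KRT6A level at 247 CPM. With no replicate block the median was 0.09 and the adjusted p 0.0821, and with limma-voom the median was 0.13. It was 0.36 without replicate 6 (adjusted p 1.08e-08), and over 26 members it was 0.36 with DESeq2 and 0.34 with no filter on low counts. The basal cell list, marked by KRT5, lay at 0.50 in pair 1 and between -0.08 and 0.05 in the other pairs.

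The multiciliogenesis list, regulators of the program that builds motile cilia, passed camera as lower: 3 of 15 members were higher, the median log2 fold change was -0.15 and the adjusted p in camera was 0.00491, or 0.977 with an estimated correlation. TP73 was at 49.5 ± 12.6 CPM in control and 44.7 ± 10.7 CPM in periostin, STIL at 11.5 ± 2.02 and 9.70 ± 2.04 CPM, RFX2 at 48.5 ± 15.0 and 42.4 ± 16.2 CPM and RFX3 at 77.0 ± 22.1 and 69.8 ± 21.7 CPM (SD, n = 6). The list mean was below 0 in 4 of 6 pairs, at -0.70 in pair 1, -0.36 in pair 3, -0.07 in pair 2 and -0.04 in pair 5, and was 0.20 in pair 4 and 0.12 in pair 6. Of 15 members, 0 were higher in pair 1, 7 in each of pairs 2 to 5 and 4 in pair 6. The sign of the mean therefore did not follow the members in pairs 4 and 6. Without replicate 1 the median was -0.08 and the adjusted p was 0.303. With no replicate block it was 0.0605. No member had an unadjusted p under 0.05, and 0 passed adjusted over the list alone.

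The NRF2 and oxidative stress list, enzymes of glutathione synthesis and detoxification, was lower as a group, with 0 of 19 members higher, a median log2 fold change of -0.06 and an adjusted p of 0.000861 in camera. Its adjusted p was 0.274 in camera with an estimated correlation, which at 0.006 was not above the preset 0.01. The higher p therefore did not come from members that varied together more than the preset assumes. NQO1 (chromosome 16, 69706996 to 69726951, minus strand) was at 314 ± 32.4 CPM in control and 294 ± 27.5 CPM in periostin, GCLC at 354 ± 33.1 and 325 ± 24.5 CPM, ALDH3A1 at 2629 ± 524 and 2394 ± 474 CPM and the cystine transporter SLC7A11 at 12.9 ± 10.1 and 7.18 ± 3.04 CPM (SD, n = 6). The list mean was below 0 in 6 of 6 pairs, by -0.17 to -0.05 on the log2 scale, and the list median in 5 of 6; in pair 2, 10 of 19 members were higher. SLC7A11 weighed on these means, with log2 differences of -1.83 in pair 1 and -1.53 in pair 2. Without it, a setting chosen after its values were seen, the means were between -0.14 and -0.02 and the adjusted p in camera was 0.00289. Unadjusted p was under 0.05 for 3 members, and 0 passed adjusted over the list alone. With no replicate block this was the 1 list that passed, with an adjusted p of 0.0261 in camera.

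**Figure D2:**
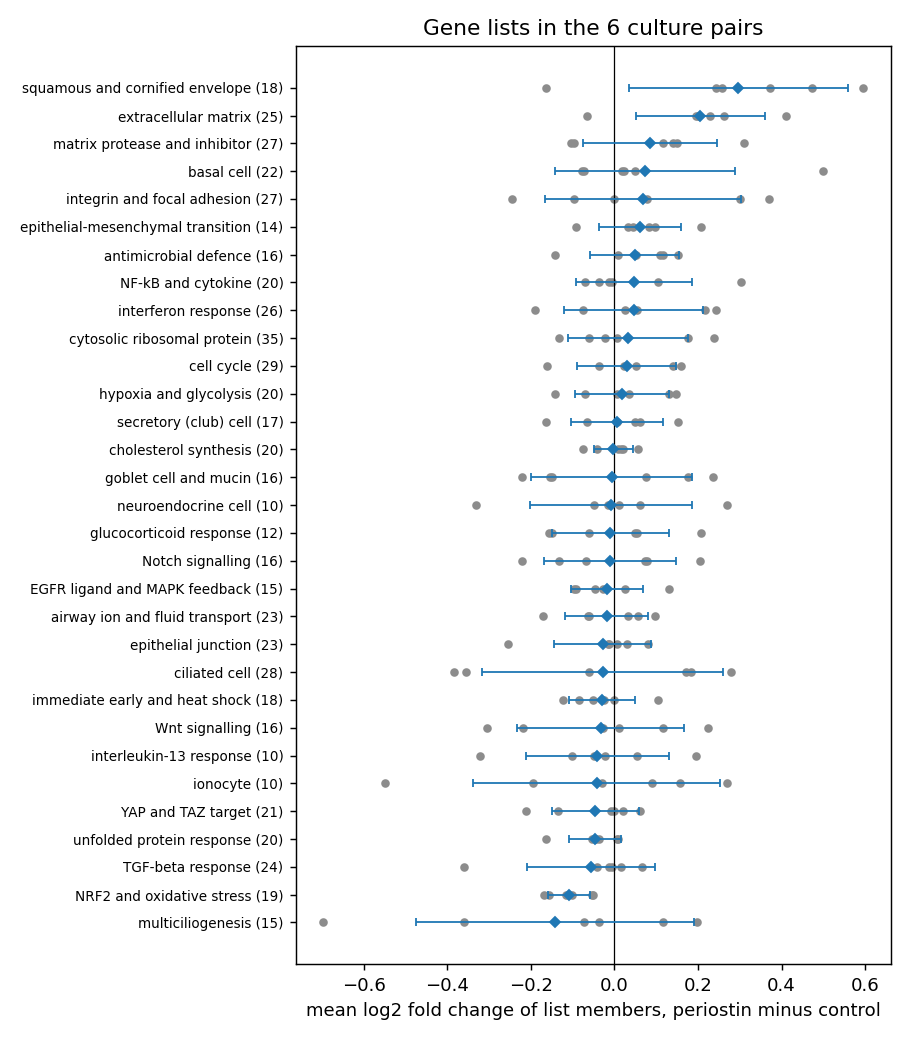
Mean log2 fold change of the tested members of each gene list (x axis) in each of 6 culture pairs (grey points), with the mean and SD over the 6 pairs (blue diamond and bar); the number of tested members stands in parentheses. The squamous list lies above 0 in 5 of 6 pairs, as do the extracellular matrix, epithelial-mesenchymal transition and antimicrobial defence lists. The NRF2 list lies below 0 in 6 of 6 pairs, and every other list has pairs on both sides of 0.

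Markers of the basal and differentiated airway cell types did not separate the groups in camera over the 6 pairs. The ciliated cell list had 16 of 28 members higher (median log2 fold change 0.02, adjusted p 0.925), with the axonemal genes HYDIN at 57.1 ± 25.02 against 70.6 ± 24.8 CPM and CFAP44 at 94.7 ± 28.4 against 101 ± 36.6 CPM. FOXJ1, the regulator of motile cilia, was at 442 ± 124 CPM in control and 437 ± 165 CPM in periostin (SD, n = 6). The basal list had 15 of 22 members higher (0.05, adjusted p 0.325), with KRT17 at 90.2 ± 34.7 against 107 ± 26.7 CPM and CAV2 at 92.9 ± 14.6 against 105 ± 18.0 CPM. KRT5 was at 788 ± 282 and 846 ± 257 CPM. Without replicate 2 the basal list passed camera as higher, with an adjusted p of 0.0301. Over 6 pairs its camera adjusted p with an estimated correlation was 0.977. The secretory (club) cell list had 7 of 17 members higher (-0.001, adjusted p 0.96), and its marker SCGB1A1 ranged widely, at 1058 ± 719 and 1344 ± 1072 CPM, as did MUC1 at 199 ± 121 and 129 ± 23.9 CPM and BPIFA1 at 7634 ± 7144 and 8054 ± 7352 CPM. In the goblet cell and mucin list 7 of 16 members were higher (-0.04, adjusted p 0.96), with MUC5B at 21.4 ± 23.5 and 17.1 ± 12.5 CPM and CEACAM6 at 181 ± 81.5 and 191 ± 84.6 CPM, while MUC5AC was too low to test. Of the ionocyte list 5 of 10 were higher (-0.02, adjusted p 0.925), with CFTR at 30.5 ± 5.46 and 29.5 ± 9.002 CPM. The neuroendocrine list had 6 of 10 higher (0.02, adjusted p 0.96), with CPE at 18.5 ± 7.06 and 19.3 ± 7.01 CPM.

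The pairs differed in these markers. In pair 1 KRT5 was at 564 CPM in control and 1125 CPM in periostin, FOXJ1 at 475 and 311 CPM and CFTR at 28.3 and 14.6 CPM; these 3 genes were chosen after their values were seen. The mean of the ciliated cell list was -0.39 in pair 1 and -0.36 in pair 6 on the log2 scale. SCGB1A1 and MUC1 differed most in pair 2, with log2 differences of 1.6 and -2.18. Without replicate 1 the log2 fold change of FOXJ1 was 0.07, that of KRT5 was -0.06 and that of CFTR was 0.07, each opposite in sign to the value over 6 pairs. The ciliated cell list passed camera as higher without replicate 1, with an adjusted p of 0.00286, though its means in the other pairs ranged from -0.36 to 0.28. Its estimated correlation was 0.654, and over 6 pairs the adjusted p with that correlation was 0.977.

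**Figure D3:**
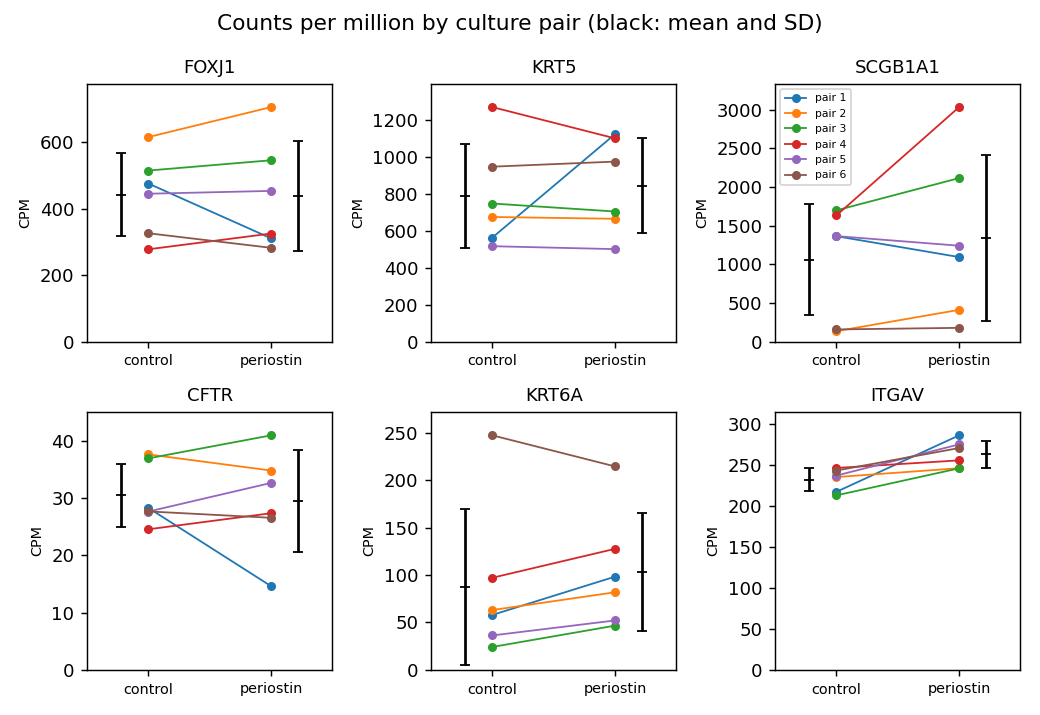
CPM (y axis, from 0) of FOXJ1, KRT5, SCGB1A1, CFTR, KRT6A and ITGAV in control and periostin cultures, with a line for each of 6 pairs and the mean and SD in black. ITGAV is higher with periostin in 6 of 6 pairs and KRT6A in 5 of 6, while FOXJ1, KRT5 and CFTR differ most in pair 1.

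Markers of other cell types were mostly too low to test. The tuft cell list had 4 tested members of 14, among them IRAG2 at 10.015 ± 7.53 and 12.6 ± 7.57 CPM and POU2F3 at 1.76 ± 0.75 and 1.94 ± 0.20 CPM. The fibroblast list had 3 of 13 tested, with COL1A1 at 2.08 ± 1.21 and 1.68 ± 0.87 CPM. Of 16 immune cell markers 3 were tested, with CD68 at 4.98 ± 1.14 and 5.32 ± 0.89 CPM, and of 10 endothelial markers 2 were tested, with KDR at 15.8 ± 6.91 and 15.5 ± 8.41 CPM (SD, n = 6 each).

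Among lists tied to matrix and adhesion, the extracellular matrix list had 18 of 25 members higher, with a median log2 fold change of 0.11 and an adjusted p of 0.215 in camera. Its mean was higher in 5 of 6 pairs. In pair 4, where the mean was largest at 0.41, 12 of 25 members were higher, against 9 in pair 2 and 17 to 19 in the other pairs. Without replicate 2 this list passed, with an adjusted p of 0.00488, while over 6 pairs the adjusted p with an estimated correlation was 0.977. Tenascin C (TNC; chromosome 9, 115019578 to 115118257, minus strand) was at 0.99 ± 0.80 CPM in control and 2.14 ± 0.70 CPM in periostin (SD, n = 6), higher in 6 of 6 pairs with an unadjusted p of 0.046 and with under 1 count on curated models in 2 control libraries, and THBS1 was at 23.6 ± 7.39 and 27.7 ± 5.44 CPM. The integrin and focal adhesion list had 12 of 27 higher (median -0.01, adjusted p 0.949). Of matrix proteases and inhibitors 17 of 27 were higher (0.06, adjusted p 0.473), with SERPINE2 at 1.54 ± 0.60 and 2.23 ± 1.27 CPM and PLAT at 2.41 ± 1.36 and 3.91 ± 3.33 CPM. The TGF-beta response list was split, 12 of 24 higher (0.01, adjusted p 0.949), with IGFBP7 at 85.3 ± 25.3 and 95.6 ± 21.7 CPM and LTBP2 at 5.22 ± 1.21 and 2.96 ± 2.13 CPM. LTBP2 was at 0 CPM in periostin replicate 2, and its log2 difference was -4.65 in pair 2 and 0.19 in pair 1. Of YAP and TAZ targets 6 of 21 were higher (-0.07, adjusted p 0.325), with NUAK2 at 13.97 ± 3.46 and 12.1 ± 1.502 CPM and AJUBA at 66.0 ± 6.23 and 61.5 ± 3.88 CPM. The epithelial-mesenchymal transition list had 10 of 14 higher (0.04, adjusted p 0.474), with TPM2 at 11.8 ± 2.56 and 13.7 ± 3.00 CPM. In the epithelial junction list 11 of 23 were higher (-0.01, adjusted p 0.949), with CLDN10 at 0.93 ± 0.40 and 0.40 ± 0.27 CPM and CLDN8 at 60.2 ± 5.75 and 66.5 ± 10.5 CPM.

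Inflammatory and defence lists also did not pass camera. POSTN is a marker of the interleukin-13 response of airway epithelium, and of that list 10 of 22 members were tested, 4 of them higher (median log2 fold change -0.01, adjusted p 0.925); SERPINB2 was at 28.0 ± 13.6 and 31.3 ± 5.55 CPM and NOS2 at 86.7 ± 83.5 and 73.2 ± 57.3 CPM, and CLCA1 and CCL26 were too low to test. The NF-kB and cytokine list had 13 of 20 higher (0.01, adjusted p 0.637), with PTGS2, the inducible cyclooxygenase, at 2.72 ± 0.63 and 3.62 ± 0.59 CPM and TNFAIP2 at 40.2 ± 12.01 and 35.4 ± 10.1 CPM. The interferon response list had 18 of 26 higher (0.07, adjusted p 0.325), while MX1 was lower in 5 of 6 pairs, at 18.9 ± 5.21 and 10.8 ± 4.24 CPM, and IFIT1 was at 15.3 ± 4.08 and 17.8 ± 2.15 CPM. Curated accessions held 87.9% of the matched MX1 counts in control and 74.7% in periostin, so its assignment between models is uncertain. In the antimicrobial defence list 7 of 16 were higher (-0.001, adjusted p 0.925), with S100A8 at 6.22 ± 5.65 and 6.67 ± 3.52 CPM and S100A9 at 96.0 ± 39.8 and 106 ± 27.2 CPM. The glucocorticoid list had 5 of 12 higher (-0.02, adjusted p 0.949), with ZBTB16 at 103 ± 20.4 and 95.1 ± 18.4 CPM.

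In the lists for signalling and metabolism the medians lay near 0. The airway ion and fluid transport list had 8 of 23 members higher (median log2 fold change -0.06, camera adjusted p 0.474), with the potassium channel KCNQ1 at 55.1 ± 4.83 and 50.8 ± 7.005 CPM and SLC4A8 at 75.6 ± 31.5 and 66.5 ± 30.0 CPM. Of the Wnt list 9 of 16 were higher (0.01, adjusted p 0.925); its receptor FZD6 was at 174 ± 12.4 and 192 ± 20.5 CPM and its ligand WNT4 at 109 ± 25.02 and 95.5 ± 26.2 CPM. Limma's fry was also used on all 31 lists to ask whether members differ in either direction. The Wnt list, at an adjusted p of 0.00632 in fry, was the 1 list of 31 that passed. In it 5 members had an unadjusted p under 0.05 in edgeR. Adjusted over the list alone, 0 Wnt members passed, and the smallest edgeR adjusted p, 0.0813, was the lowest of the lists with tested members. The Notch list had 7 of 16 higher (-0.03, adjusted p 0.949), with DLL1 at 46.6 ± 8.92 and 41.6 ± 7.74 CPM and RBPJ at 28.4 ± 9.43 and 35.1 ± 4.54 CPM. EGFR ligands and MAPK feedback genes had 8 of 15 higher (0.02, adjusted p 0.925), with SPRED2 at 17.1 ± 3.32 and 14.5 ± 2.10 CPM. The cell cycle list had 17 of 29 higher (0.01, adjusted p 0.949), with CCNB2 at 2.81 ± 0.93 and 1.95 ± 0.30 CPM. Immediate early and heat shock genes had 7 of 18 higher (-0.03, adjusted p 0.473), with KLF4 at 15.2 ± 2.92 and 13.7 ± 2.00 CPM. The unfolded protein response list had 7 of 20 higher (-0.02, adjusted p 0.473), with ASNS at 25.7 ± 9.79 and 21.3 ± 5.37 CPM and CHAC1 at 8.79 ± 2.55 and 7.63 ± 2.62 CPM. Cholesterol synthesis had 8 of 20 higher (-0.01, adjusted p 0.96), with FDPS at 78.4 ± 12.995 and 84.7 ± 5.97 CPM. Hypoxia and glycolysis had 10 of 20 higher (-0.002, adjusted p 0.925), with PFKFB3 at 106 ± 15.7 and 94.4 ± 14.9 CPM and ADM at 7.30 ± 1.502 and 6.33 ± 1.98 CPM. The cytosolic ribosomal protein list had 32 of 35 higher by little (0.04, adjusted p 0.209), with RPL10A at 471 ± 49.1 and 496 ± 24.2 CPM (SD, n = 6 throughout). This list passed camera as higher without replicate 3 (adjusted p 0.0182) and without replicate 5 (adjusted p 0.00121), but its members varied together (estimated correlation 0.895), and over 6 pairs the adjusted p with that correlation was 0.977. All 35 members were higher in pairs 1 and 2, 5 in pair 3 and 0 in pair 5, and the list mean was above 0 in 3 of 6 pairs.

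Over the lists 592 genes were tested, and by edgeR 0 passed the threshold over all genes and 0 adjusted over the list alone. Camera passed 3 of 31 lists with the preset correlation and 0 with an estimated correlation, and fry for a shift in one direction passed 0.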

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

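The leave-one-pair tests of the 3 lists, the exact sign-flip tests of pair means and medians and the tests without SLC7A11 were chosen after the camera results had been seen. For the arrangements of the labels, the squamous minus basal test and the matched random lists, the bounds were written before their results. The squamous minus basal test and the matched random lists concern lists that camera had singled out, so they do not stand apart from the camera results.

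The real number of genes past the threshold in edgeR was 0, which any arrangement of the labels matches, so the counts of arrangements decide nothing about it. They were 32 of 32 for labels swapped within pairs, with a highest other count of 2, and 100 of 100 for splits of the 12 libraries with no replicate block, with a highest other count of 1. At an unadjusted p under 0.05, 13 of the 32 within-pair arrangements gave as many genes as the real 608, over a range of 264 to 1658. For gene lists past camera, 19 of the 32 within-pair arrangements gave as many as the real 3, and the highest other count was 11. Chance was therefore not excluded for the number of lists.

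The squamous and cornified envelope list lay higher with periostin. Against a single culture pair as the source of the camera call stands the highest adjusted p with 1 pair left out, 0.00276 (without replicate 2). This used the preset correlation. With an estimated correlation the list did not pass camera over the 6 pairs (adjusted p 0.875). Chance direction of co-varying members stays open, as the exact sign-flip p was 0.062. A larger share of basal cells in the periostin cultures also stays open over the 6 pairs. The pair means of the squamous list minus the basal list were 0.223 ± 0.362 (SD of 6 pairs), above 0 in 4 of 6 pairs. Their exact sign-flip p was 0.219. In pairs 2 to 5 the squamous list lay at 0.24 to 0.60 and the basal list between -0.08 and 0.05. There the basal list moved less than the squamous list, but these pairs were set apart after their values were seen. They therefore do not decide on a larger basal share. In pair 1 the basal list lay at 0.50, above the squamous list at 0.26. In pair 6 the squamous list was lower, at -0.16. An effect of periostin on squamous genes remains a hypothesis. Over 6 pairs the basal cell share cannot be told apart from it. The sign-flip test did not separate the squamous list from the basal list, and cell shares were not measured.

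For the multiciliogenesis list, which camera passed as lower, a single pair may account for the camera call. The adjusted p was 0.303 without replicate 1, and the exact sign-flip p of the 6 pair means was 0.406. Those means were above 0 in pairs 4 and 6, although 7 and 4 of 15 members were higher there. In pair 1 the multiciliogenesis list lay at -0.70, the ciliated cell list at -0.39 and the basal cell list at 0.50. A link between these lists was not tested.

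The mean of the NRF2 and oxidative stress list was below 0 in 6 of 6 pairs, and in 6 of 6 without SLC7A11, though its median was below 0 in 5 of 6 and 10 of 19 members were higher in pair 2. Against a single pair as the source of the camera call stands the highest adjusted p with 1 pair left out, 0.0182 (without replicate 3). This too used the preset correlation, and with an estimated one the list did not pass camera over the 6 pairs (adjusted p 0.274). That estimate, 0.006, was not above the preset 0.01, so the higher p does not show that the members varied together. Against a trend of all genes of the same abundance stands the list median, at the 0.08th percentile of 10000 random lists matched on mean expression. Chance direction stays open although the exact sign-flip p was 0.031: that was the smallest p that 64 sign flips can give, the bound of 0.05 set before the result took no account of the 31 lists tested, of which chance alone would bring 0.97 to that p, and 1 reached it. With the pair medians in place of the means the exact sign-flip p was 0.062. The effect is small, with a median log2 fold change of -0.06, and periostin as its source is a hypothesis.

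Of 189 groups of 6 values tested for a library far from the rest, 17 had one, and chance gives about 9.4. In control replicate 2, ribosomal RNA took 6.7% of counts (1.52% to 3.19% in the other control libraries), and SNORA84 was at 5.39 CPM (2.47 to 3.19), NUAK2 at 20.7 CPM (11 to 13.9) and ASNS at 45.2 CPM (18.9 to 25.3). Control replicate 1 stood apart for ZNF704 at 6.88 CPM (3.97 to 4.76) and COL1A1 at 4.52 CPM (1.27 to 1.89). SNHG21 in control replicate 3 was at 1.0 CPM (0.484 to 0.634) and POU2F3 in control replicate 5 at 3.24 CPM (1.16 to 1.70). Among periostin libraries, replicate 3 had the lowest total, 16 M counts (18.0 to 18.8 in the others). In periostin replicate 4, ATP2B1 was at 0.123 CPM (9.36 to 22) and LPIN2 at 28.5 CPM (12.7 to 16.2). Periostin replicate 1 stood apart for SNHG21 at 0.789 CPM (1.22 to 1.48), ITGB6 at 56.9 CPM (20 to 27.5) and THBS1 at 38.5 CPM (23.2 to 26.9). SNORA84 in periostin replicate 6 was at 1.31 CPM (1.93 to 2.29), MUC1 in periostin replicate 2 at 85.4 CPM (126 to 156) and GCLC in periostin replicate 3 at 371 CPM (300 to 324).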

How the results depend on the processing

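Protein-coding genes only and the exact sign flips of the pair means were chosen after the data were seen; the other settings were planned. The number of genes past the threshold was 0 in the main edgeR test and 0 in the settings tried, except for 2 with DESeq2 (ATP2B1 and LPIN2, both raised) and 1 with no filter on low counts (ATP2B1, raised); the number lowered was 0 throughout. With no replicate block, where the pairing by donor is not used, 0 genes and 1 list passed (NRF2), against 3 lists in the main test. An estimated correlation in camera and fry for a shift in one direction each passed 0 lists, while fry for either direction passed 1 (Wnt). Exact sign flips passed 0, which their smallest p of 0.031 over 31 lists fixes unless most lists reach it, so this says nothing about the lists. The number of lists ranged from 3 to 5 with 1 pair left out: without replicate 2 it was 5, with the basal cell (adjusted p 0.0301) and extracellular matrix lists added, without replicate 3 and without replicate 5 it was 4, with the cytosolic ribosomal protein list added (adjusted p 0.0182 and 0.00121), and without replicate 1 multiciliogenesis was replaced by the ciliated cell list. Of 1434 values of 103 named genes, 1420 kept their direction and 14 did not. Most of these genes were named for a small unadjusted p in the same libraries that the alternatives reuse. Kept directions were therefore likely from the start and are no independent evidence. BPIFA1 was reversed at 0.077 with no replicate block. With 1 pair left out the log2 fold change ranged from -0.217 to 0.354 for PRRX1, -0.033 to 0.18 for LYZ, -0.123 to 0.005 for KDR, -0.09 to 0.046 for VWF, -0.112 to 0.066 for FOXJ1, -0.063 to 0.163 for KRT5, -0.33 to 0.121 for MUC5B, -0.152 to 0.074 for CFTR and -0.177 to 0.046 for BPIFA1; the cause was not tested. POSTN stayed lower at pseudocounts of 0.1 and 0.01 TPM (exact sign-flip p 0.219 in both) and with each pair left out, where the mean log2 difference ranged from -0.098 to -0.024. The counts limit POSTN, ITGB3, TNC, CRB1, SNHG21, SERTAD2-AS1, CLDN10 and PRRX1, which lie near or below 1 CPM in at least 1 group. They also limit TBC1D30, which lay at 0.92 CPM in periostin.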

Other observations

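Although the labels name an mRNA kit, RNAs that carry no poly(A) tail took a large part of the gene counts. The 6 RNAs RN7SL1, RN7SL2, RN7SK, RPPH1, RMRP and SNORD3A summed to 12.9 ± 0.65% of gene counts in control and 13.3 ± 0.40% in periostin (SD, n = 6), between 11.8% and 13.8% per library. RN7SL1, the RNA of the signal recognition particle, took 4.66 ± 0.41% in control and 4.73 ± 0.24% in periostin. These 6 RNAs were chosen after their values were seen.

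MUC5B and SCGB1A1 varied between pairs far more than between groups. The periostin over control ratio of MUC5B was 0.46 in pair 2 and 2.31 in pair 4, and that of SCGB1A1 was 3.04 in pair 2 and 0.80 in pair 1.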
